A study of Mus musculus with 2 samples.

How the data were processed

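H3K27me3 was measured by chromatin immunoprecipitation and sequencing in 2 biological replicates of E12.5 midbrain from B6NCrl mice, pools of 120 embryos in replicate 1 and 88 in replicate 2. The replicates form 1 group, and the comparisons are within it. The 4 deposited files are peak lists of 10 fields on mm10, made by the authors for replicate 1, for replicate 2, for both replicates pooled, and as a replicated list. Per the labels, replicate 1 was called against 1 control file and replicate 2 against 2, of which 1 is shared, and the pooled list used 2. The peak caller, its settings and the overlap rule of the replicated list are not given in the sources used here.

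Each deposited peak holds a score, a fold over control, a -log10 p and a -log10 q, and a summit offset in bases (the unit other) per the labels, which give the format of the lists. The deposited fold ratio is the authors' value and was used only within a list. Every list held peaks with a -log10 p above 2 only, and 98.7% of replicated peaks had a -log10 q of at least 2. The score and the summit offset were read but not used. The files hold no counts, so the depth per replicate is unknown and no interval that needs it was given.

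All 77572 replicated peaks were in the pooled list. Of these, 64101 (82.6%) overlapped a peak of each replicate by at least 50% of either peak and 13471 did not. Of the replicated peaks 13007 touched no peak of at least 1 replicate's own list, so the rule behind the list was not recovered from the files. Peaks lay on the primary chromosomes except 2 peaks of replicate 1 on scaffolds, which were left out of chromosome values.

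The annotation was GENCODE M21 on the same assembly. It gave 21911 protein-coding genes after 27 repeated symbols were dropped, each with 1 start, the most upstream end of the gene. A gene was called marked when peaks of the replicated list covered at least 500 of the 2000 bases from 1 kb upstream to 1 kb downstream of its start. A promoter was called CpG-rich when its CpG observed over expected was at least 0.6 and its GC content at least 55%. The error of a value is the SD between the lists of the 2 replicates. Neighbouring genes share peaks, so genes are not independent replicates and each p is across genes.

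The 26 gene lists, 7 contrasts between lists, 5 lists for long domains, the settings, the tests and most alternatives were fixed before the data were examined. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 26 lists, and the 7 contrasts and 5 domain tests were adjusted in the same way. A list was called at an adjusted p under 0.05. Odds ratios have 95% conditional intervals, and only the finite bound is given where all or no members were marked. For log2 odds ratios 0.5 was added to each count, and for shifts and bins of CpG content the log2 ratio of marked to expected members, with 0.5 added to each, was used. Domains were made by joining replicated peaks less than 3 kb apart and were called long with at least 20 kb covered. A peak was called shared when the other replicate covered at least 50% of it. Overlaps were set against 100 circular shifts of the peaks along each chromosome.

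Genes were named by a rule with 4 parts. It took the 20 genes whose window held the replicated peaks of highest fold, whether or not the gene was marked. It also took up to 4 marked and up to 4 unmarked genes of each list, the genes of the 20 longest domains, and 13 genes chosen in advance. The gene families, miRNAs and unmarked genes in long domains among the other observations were chosen after their values were seen.

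The alternatives were the pooled list, the list of each replicate alone (without the other replicate), stricter -log10 q of at least 2 and fold of at least 3, windows of 0.5 kb and 2.5 kb each side, any overlap of 1 base, at least 1000 bases covered, any transcript start, backgrounds without the tandem families or with CpG-rich promoters only, autosomal genes only, members within 100 kb counted once, and 1000 circular shifts. For shared peaks they were 1 base, 80% of the peak, 50% of both peaks, a -log10 q of at least 2 and equal numbers of peaks. For domains they were gaps of 1 kb and 10 kb, at least 10 kb covered and the pooled list. With windows of 0.5 kb and 2.5 kb each side, the minimum of covered bases was scaled in proportion to the window. Alternatives chosen after the data were seen were peaks overlapping each replicate by at least 50%, autosomes only for promoter counts and long domains, and 10 bins of CpG content with 20000 permutations.

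Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, bedtools 2.31.1 and samtools 1.23.1, and plots used matplotlib 3.10.9. The code was tested on simulated data, where all 4000 of 4000 planted marked genes and 200 of 200 planted domains were recovered. Planted peaks and domains were made to meet the calling rules, so their recovery checks the code only. In 50 rounds with 20 raised and 20 random lists, 1000 of 1000 raised lists and 29 of 1000 random lists were called, 2.82% of all calls. Each raised list held the same number of planted marked genes. Random lists were drawn gene by gene, so this share does not apply to lists of neighbouring genes.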

Results

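H3K27me3, the histone methylation that Polycomb complexes place on silenced genes, was profiled by chromatin immunoprecipitation and sequencing in the midbrain of E12.5 mouse embryos of the B6NCrl strain. The samples form 1 group of 2 biological replicates, each a mixed-sex pool of healthy embryos, 120 for replicate 1 and 88 for replicate 2. The deposited peak lists hold 161204 peaks covering 74.6 Mb in replicate 1 and 144428 peaks covering 67.9 Mb in replicate 2. Calling on both replicates together gave a pooled list of 235768 peaks, of which 77572, covering 70.7 Mb or 2.59% of the genome, form the replicated list. A replicated peak was 566 bases long at the median and up to 55937 bases long, and its median fold over control was 3.03. The depth behind each list is unknown, because the lists hold no read counts. The labels give no other tissue, stage or treatment, so gene groups, regions and replicates were compared. Positions are those of the mouse assembly mm10, and the annotation is GENCODE M21.

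The first comparison asked which protein-coding promoters carried the mark in midbrain. The fold given for a gene is the highest of any replicated peak that touches its window. It describes the whole peak, which can reach beyond the window and be shared by neighbouring genes. The highest fold over control at any marked promoter, 21.9, was at Wnt3a (chromosome 11, 59248033 to 59290752), a Wnt ligand of the dorsal neural tube, whose promoter window was covered over 100% ± 0 of its length (SD, n = 2). Next in fold came Fam43b with 20.1, Grwd1 with 20.0 and Egr3, an immediate early transcription factor, with 18.8. T, the mesoderm regulator Brachyury, had a fold of 18.1, Hmx1, a homeobox gene of sensory ganglia, 18.1, and Cdx2, a regulator of posterior and intestinal fate, 17.6. The alpha adrenergic receptor gene Adra2c had a fold of 17.7 and the lung and gut mesenchyme regulator Foxf1 one of 17.4. At Grwd1 the peak lay at the edge of the window, 34.2% of which was covered by replicated peaks, and none of the gene body was. The actin gene Actb, the glycolytic gene Gapdh, the TATA-binding protein gene Tbp and the purine salvage gene Hprt had no covered base in the window in either replicate.

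Of 21911 protein-coding genes, 4249 (19.4%) had at least 500 of the 2000 bases around the start covered by replicated peaks and are called marked here. Each replicate's own list marked 18.0% ± 0.507 of genes (SD, n = 2), and 3481 of the 3492 genes marked by both lists were also marked by the replicated list. In the other direction, 3481 of the 4249 marked genes reached 500 covered bases in both replicates' own lists, and the rest fell short in at least 1. CpG-rich promoters were marked in 1952 of 8414 cases (23.2%) and other promoters in 2297 of 13497 (17.0%). The other promoters include nearly all of the 1092 olfactory and 326 vomeronasal receptor genes, of which 2 and 0 were marked, and this lowers their share. The window was fully covered at 1245 genes and touched by at least 1 base at 5546.

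Regulators of the body axis and of other parts of the nervous system were marked almost throughout. All 39 Hox genes, which set position along the trunk, were marked, at a median fold of 11.8. Hoxa9 had 76.0% ± 4.53 of its window covered (SD, n = 2) and a fold of 17.3, and Hoxd13, the last gene of its cluster, 100% ± 0 and a fold of 9.59. All 22 hindbrain and spinal cord regulators were marked, among them Ptf1a with a fold of 14.6, Mnx1, a motor neuron gene, with 13.8, and Gbx2, which sets the hindbrain side of the isthmus, with 13.0. Of 27 forebrain patterning genes 25 were marked, led by Fezf2 with a fold of 14.3, Six3 with 14.2 and Lhx6 with 13.8. The telencephalic regulator Foxg1 had 89.1% ± 6.01 of its window covered (SD, n = 2), whereas Bcl11b and Hesx1 were the pair of forebrain genes not marked. Of all other protein-coding genes 19.2% to 19.3% were marked, and by Fisher's exact test the adjusted p was 9.31e-28 for Hox genes (lower 95% bound of the odds ratio 42.3). The adjusted p was 8.82e-16 for hindbrain and spinal cord regulators (lower bound 22.9) and 1.27e-15 for forebrain patterning genes (odds ratio 52.2, 95% interval 13.0 to 455), also by Fisher's exact test. In these 3 lists every share was the same in both replicates. Hox genes lie in 4 clusters and share peaks, so the members of the list are not independent replicates, and a p across genes treats them as if they were.

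**Figure D1:**
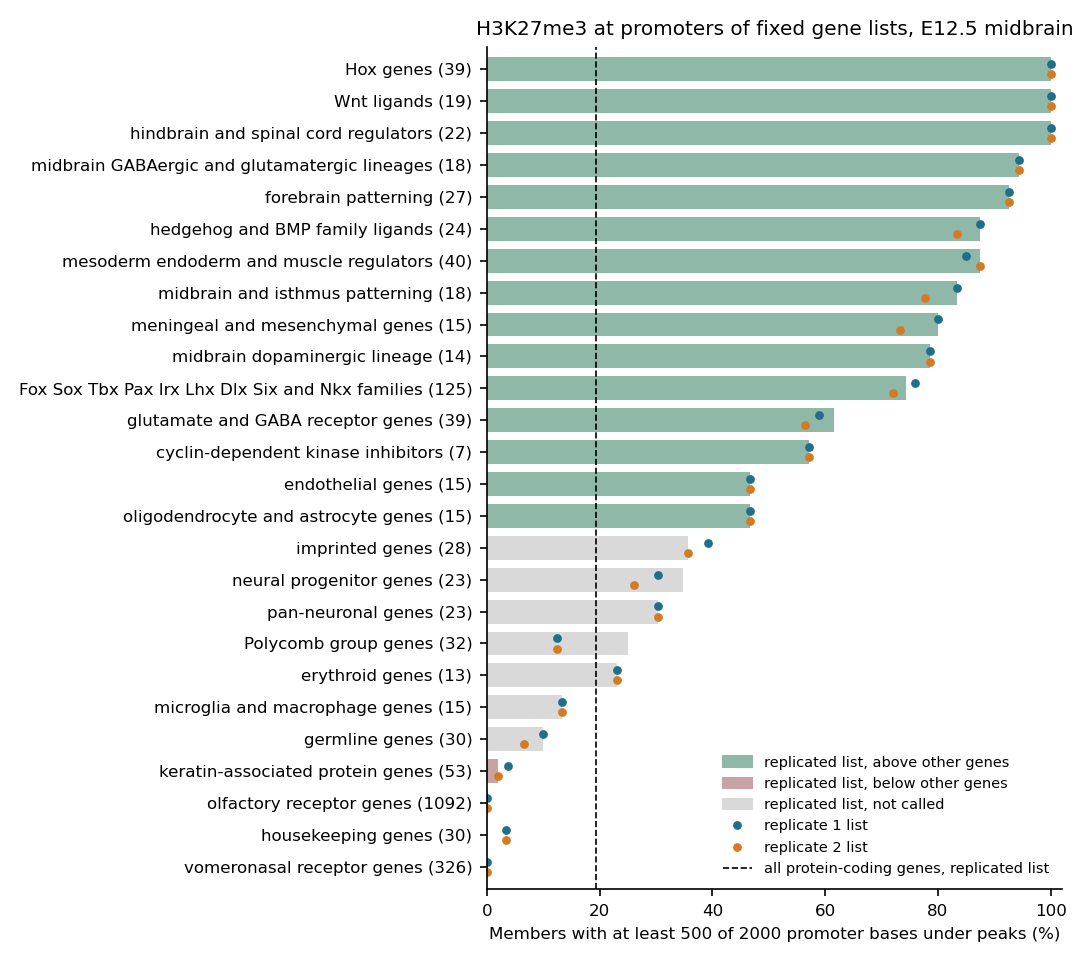
Share of the members of each of 26 gene lists whose promoter was marked by replicated peaks, in percent on the x axis as bars, with points for the 2 replicate lists and a line at 19.4% for all protein-coding genes. Hox genes, Wnt ligands and hindbrain and spinal cord regulators stood at 100%, neural progenitor genes at 34.8% and housekeeping genes at 0%.

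Genes that pattern the midbrain itself carried the mark as well. Of 18 midbrain and isthmus patterning genes 15 were marked, in 80.6% ± 3.93 of members by the replicates' own lists (SD, n = 2). Wnt1, the isthmus signal, had a fold of 16.7, Pax2, an early isthmus factor, 12.2, Pax5, its relative, 10.8, and Lmx1b 10.7. Fgf8, the isthmic organiser signal, had 100% ± 0 of its window covered and a fold of 9.78. En1 (chromosome 1, 120602418 to 120607992), which maintains midbrain and dopaminergic neurons, had 76.9% ± 4.00 of its window covered (SD, n = 2) and a fold of 6.50. En2 had 71.6% ± 2.44 (SD, n = 2) and a fold of 8.13. Otx2 (chromosome 14, 48657677 to 48673819), the factor that defines forebrain and midbrain, had 41.8% ± 3.15 (SD, n = 2), a fold of 3.78 and 11.8% of its gene body covered. Otx1, Meis2 and Cnpy1 were not marked. Otx1 had no covered base in its window but 70.9% of its gene body covered. By Fisher's exact test the adjusted p of the list was 1.96e-08 (odds ratio 20.8, 95% interval 5.89 to 112), and more members than other genes were marked in both replicates.

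The neuronal lineages of the midbrain were marked in most of their members. In the dopaminergic lineage 11 of 14 genes were marked, among them the proneural gene Neurog2 with a fold of 10.4, Pitx3, which dopaminergic neurons need, with 10.1 and the floor plate factor Foxa2 with 100% ± 0 of its window covered (SD, n = 2). The dopamine synthesis genes Th, with 2.73% ± 3.85 of its window covered (SD, n = 2), and Ddc, with 0% ± 0, were not marked, nor was Aldh1a1. In the GABAergic and glutamatergic lineages 17 of 18 genes were marked, led by the GABAergic selector Helt with a fold of 14.6 and the vesicular GABA transporter Slc32a1 with 13.3. The exception was Gad1, the enzyme that makes GABA, with an uncovered window and 31.0% of its body covered. By Fisher's exact test the adjusted p was 5.44e-06 for the dopaminergic list (odds ratio 15.3, 95% interval 4.03 to 85.3) and 2.89e-11 for the GABAergic and glutamatergic list (odds ratio 70.9, 95% interval 11.1 to 2965). Shares were the same in both replicates for each list.

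Lists of genes of dividing and of differentiating neural cells did not pass the test against other genes. Of 23 neural progenitor genes 8 were marked, among them Neurog1 with a fold of 10.4 and Pax6, a forebrain and progenitor factor, with 7.69. Sox2 and Nes, markers of neural stem cells, and Sox3 and Sox9 were not marked. The window of Sox2 was covered over 21.6% ± 21.2 (SD, n = 2), a value that differed between the replicates. Of 23 pan-neuronal genes 7 were marked, with Ina, an intermediate filament gene, at a fold of 8.86 and Nefl at 5.27, while the tubulin gene Tubb3, the microtubule genes Dcx and Map2 and Stmn2 were not. Neither list passed Fisher's exact test, with adjusted p = 0.0844 for progenitor genes (odds ratio 2.22, 95% interval 0.814 to 5.58) and 0.221 for pan-neuronal genes (odds ratio 1.82, 95% interval 0.633 to 4.68). Progenitor genes passed with promoter windows of 0.5 kb and 2.5 kb each side, and both lists passed when any transcript start was used. Pan-neuronal genes also passed among CpG-rich promoters alone.

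Lists of mesoderm, endoderm and muscle, meningeal, endothelial and glial genes passed the test against other genes. Of 40 mesoderm, endoderm and muscle regulators 35 were marked (86.2% ± 1.77 by the replicates' own lists, SD, n = 2), including T, Cdx2 and Foxf1 above. The muscle factors Myf5 and Myog, the liver factor Hnf4a and Tbx6 were among the 5 that were not. Of 15 meningeal and mesenchymal genes 12 were marked, including Twist2 with a fold of 16.7, Foxc1 with 11.4 and Pdgfra with 11.3. Of 15 endothelial genes 7 were marked, led by Sox18 with 17.8, Flt1 with 12.1 and the tight junction gene Cldn5 with 10.5, while Pecam1, Cdh5, Tek and Tie1 were not. Of 15 oligodendrocyte and astrocyte genes 7 were marked, with the lineage factors Sox10 at 12.7 and Olig2 at 12.6, while the myelin genes Plp1, Mog and Mag were not. Fisher's exact test gave an adjusted p of 1.26e-19 for mesoderm, endoderm and muscle regulators (odds ratio 29.3, 95% interval 11.4 to 95.9) and 1.41e-06 for meningeal and mesenchymal genes (odds ratio 16.7, 95% interval 4.50 to 92.1). The endothelial list and the oligodendrocyte and astrocyte list each gave 0.0220 by Fisher's exact test (odds ratio 3.64, 95% interval 1.12 to 11.5). The endothelial call was lost with the pooled list, with any overlap of 1 base and within 10 bins of CpG content, and the oligodendrocyte and astrocyte call with neighbouring members counted once.

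Blood, microglial and germline genes did not pass the test, while housekeeping genes did. Of 13 erythroid genes 3 were marked, with Epor, the erythropoietin receptor, at a fold of 9.55 and Klf1 at 5.48, and the globin genes Hba-a1, Hba-x and Hbb-bt were not. Of 15 microglia and macrophage genes the complement genes C1qa, with 63.5% ± 3.43 of its window covered (SD, n = 2), and C1qc were marked, and of 30 germline genes Tdrd5, Tdrd1 and Nanos2 were. By Fisher's exact test the adjusted p was 0.750 for erythroid genes (odds ratio 1.25), 0.750 for microglia and macrophage genes (odds ratio 0.639) and 0.283 for germline genes (odds ratio 0.462). None of 30 housekeeping genes was marked by replicated peaks, against 19.4% of other genes, and each replicate's own list marked 3.33% of them (adjusted p = 0.0036, Fisher's exact test, upper 95% bound of the odds ratio 0.543). The housekeeping call was lost without replicate 1, that is on the replicate 2 list alone, where the log2 odds ratio was -2.08 against -3.88 on the replicated list. It was also lost with windows of 2.5 kb each side.

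Lists of Wnt, hedgehog and BMP ligands and of glutamate and GABA receptors passed the test against other genes. All 19 Wnt ligand genes were marked, at a median fold of 9.46. Of 24 hedgehog and BMP family ligands 21 were marked, among them Gdf7, a roof plate signal, with a fold of 15.2, Ihh with 14.4 and Shh, the floor plate signal, with 12.3. Of 39 glutamate and GABA receptor genes 24 were marked, with the NMDA receptor subunit gene Grin2c at 13.5 and the GABA receptor gene Gabra5 at 11.5, while the AMPA receptor genes Gria2, Gria3 and Gria4 were not. In families of developmental transcription factors, among them the Fox, Sox, Tbx, Pax, Lhx and Nkx genes, 93 of 125 members were marked. The adjusted p by Fisher's exact test was 9.18e-14 for Wnt ligands (lower 95% bound of the odds ratio 19.5), 3.34e-12 for hedgehog and BMP family ligands (odds ratio 29.2, 95% interval 8.72 to 153) and 1.96e-08 for receptor genes (odds ratio 6.68, 95% interval 3.36 to 13.7). The transcription factor families gave 2.49e-39 by Fisher's exact test (odds ratio 12.3, 95% interval 8.16 to 19.1), with 74.0% ± 2.83 of members marked by the replicates' own lists (SD, n = 2).

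Kinase inhibitors passed the test, while imprinted and Polycomb group genes did not. The cyclin-dependent kinase inhibitor genes Cdkn2a, with 100% ± 0 of its window covered (SD, n = 2) and a fold of 8.92, and Cdkn2b, with 92.6% ± 1.80, were marked, as were Cdkn2c and Cdkn1a, making 4 of 7. Of 28 imprinted genes 10 were marked, led by the potassium channel gene Kcnq1 with a fold of 17.4, the transporter gene Slc22a3 with 15.5, the growth factor gene Igf2 with 12.1 and Dlk1 with 9.36. Of 32 Polycomb group genes 8 were marked, including Cbx8 with 12.3 and Cbx4 with 8.93, and the catalytic subunit gene Ezh2 and its partners Eed and Suz12 had no covered base in the window. Each replicate's own list marked 12.5% of Polycomb group genes. By Fisher's exact test the adjusted p was 0.0410 for the kinase inhibitors (odds ratio 5.55, 95% interval 0.938 to 37.9), 0.0657 for imprinted genes (odds ratio 2.31, 95% interval 0.953 to 5.29) and 0.410 for Polycomb group genes (odds ratio 1.39, 95% interval 0.538 to 3.19). The call of the 7 kinase inhibitors was lost under 6 alternatives. Imprinted genes passed with the list of either replicate alone, at a log2 odds ratio of 1.41 without replicate 1 and 1.55 without replicate 2 against 1.24 on the replicated list.

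The 3 tandem gene families tested were nearly free of replicated peaks at promoters. Only 2 of 1092 olfactory receptor genes, 0 of 326 vomeronasal receptor genes and 1 of 53 keratin-associated protein genes were marked. For these families Fisher's exact test gave an adjusted p of 1.23e-99 for olfactory receptor genes (odds ratio 0.0072), 2.76e-30 for vomeronasal receptor genes (upper 95% bound 0.0465) and 5.62e-04 for keratin-associated protein genes (odds ratio 0.0797, 95% interval 0.0020 to 0.464). Reads can map uncertainly in families with similar copies, which was not measured here and limits what these shares show. The keratin-associated call was lost with neighbouring members counted once and within 10 bins of CpG content, and the vomeronasal value turned to a log2 odds ratio of 0.14 among CpG-rich promoters, where almost no member remains. Of the 26 lists, 15 were marked more often than other genes, 4 less often, and 7 did not pass. Some lists share members, such as Pax2 and Foxg1 with the transcription factor families and Wnt1 with the Wnt ligands. Their calls are therefore not independent of each other.

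Lists were also compared with each other. Mesoderm, endoderm and muscle regulators were marked more often than neural progenitor genes, in 87.5% against 34.8% of members (adjusted p = 2.51e-04, Fisher's exact test, odds ratio 12.4, 95% interval 3.19 to 58.0), and this order held in both replicates. Hox genes (39 of 39) and midbrain and isthmus patterning genes (15 of 18) gave an adjusted p of 0.0976 by Fisher's exact test (lower 95% bound of the odds ratio 0.949). Without replicate 1 this contrast passed, with a log2 odds ratio of 4.62 against 4.16 on the replicated list. Forebrain against midbrain genes gave 0.525 (odds ratio 2.45) and hindbrain and spinal cord against midbrain genes 0.193 (lower bound 0.527) by Fisher's exact test. Pan-neuronal against progenitor genes (odds ratio 0.824) and dopaminergic against midbrain patterning genes (odds ratio 0.741) each gave 1.00 by Fisher's exact test, and Wnt against hedgehog and BMP family ligands gave 0.424 (lower bound 0.333).

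The next comparison asked where the mark formed long domains. Positions given with these domains are those of the whole domain, not of a gene, and sizes in kb are covered bases. The longest covered domain (chromosome 15, 102894357 to 103158025) held the HoxC cluster, with 229 kb covered by 72 peaks. The HoxA cluster with Evx1 (chromosome 6, 52139117 to 52329941) had 174 kb covered, the domain of Hoxb1 to Hoxb9 (chromosome 11, 96226699 to 96383889) 143 kb and the HoxD cluster with Evx2 (chromosome 2, 74639369 to 74772222) 121 kb. Outside Hox clusters, the longest domains held Prdm16 and Actrt2 (chromosome 4, 154438794 to 154679244) with 189 kb and Casz1, a zinc finger gene (chromosome 4, 148768525 to 148957405), with 164 kb. Dbx1, a spinal interneuron regulator, started with Htatip2 in a domain of 124 kb (chromosome 7, 49610485 to 49776704). The cadherin gene Cdh22 started in one of 122 kb (chromosome 2, 165094867 to 165269610). Pax2 started in a domain of 118 kb (chromosome 19, 44630583 to 44771978) and Lmx1b in one of 103 kb (chromosome 2, 33538317 to 33657126). A domain of 118 kb on chromosome X (99477086 to 99618449) held no protein-coding start.

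Joining replicated peaks less than 3 kb apart gave 26070 domains, of which 438 had at least 20 kb covered. These 438 long domains held 23.9% of all covered bases and the starts of 448 protein-coding genes, and 154 of them held no protein-coding start. All 39 Hox genes, 21 of 27 forebrain patterning genes, 16 of 22 hindbrain and spinal cord regulators, 11 of 18 midbrain and isthmus patterning genes and 20 of 40 mesoderm, endoderm and muscle regulators started in a long domain, against 1.87% to 2.00% of other protein-coding genes. In Fisher's exact test the adjusted p was 1.22e-66 for Hox genes, 1.38e-30 for forebrain, 5.96e-23 for hindbrain and spinal cord, 6.47e-15 for midbrain and isthmus, and 1.69e-23 for mesoderm, endoderm and muscle genes. Clustered genes such as the Hox genes start in the same few domains, yet each gene was counted singly. The p for Hox genes thus treats a shared domain as separate events, and the domain test was not run with neighbours counted once. Of the 448 genes starting in long domains only 15 were not marked, so the domain test largely repeats the promoter comparison. Whether list members started in long domains more often than other marked genes was not tested. The number of long domains was 268 when gaps of up to 1 kb were joined and 737 on the pooled list.

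**Figure D2:**
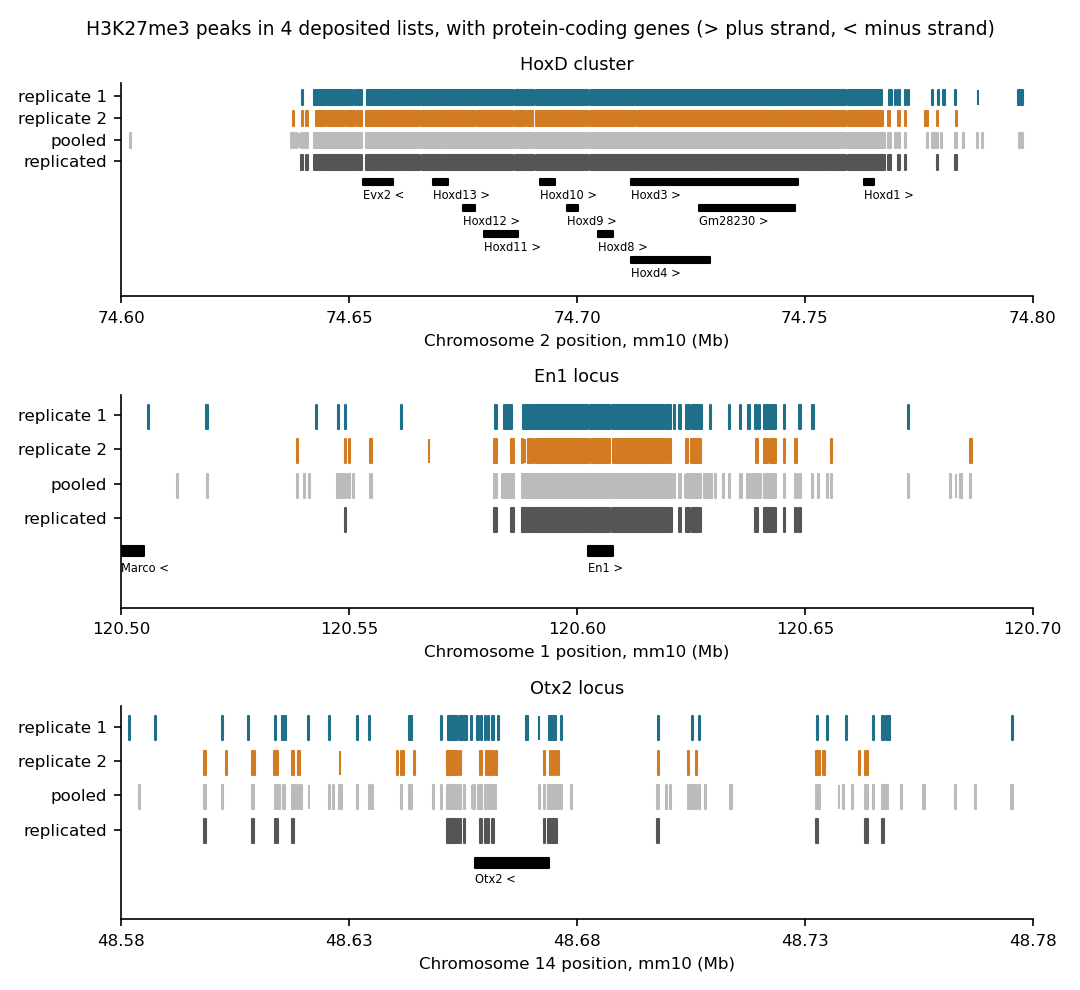
Peaks of each list in mm10 regions around the HoxD cluster (chromosome 2), En1 (chromosome 1) and Otx2 (chromosome 14), with position in Mb on the x axis, 1 line of bars per peak list and gene bodies drawn under them. Peaks covered the HoxD cluster nearly throughout, En1 over 82.1% of its body and Otx2 over 11.8%.

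Relative to the genome, covered bases were concentrated at promoters. Promoter windows made up 9.05% of bases in replicated peaks against 1.56% of the genome, a ratio of 5.80, and 5.33 ± 0.158 in the replicates' own lists (SD, n = 2). Exons outside promoters had a ratio of 1.98 (1.93 ± 0.0490), introns 1.05 (1.06 ± 0.0022) and intergenic sequence 0.737 (0.750 ± 0.0070). The distance of each class from 1 was larger than the spread between replicates, and no test was run on 2 replicates. With windows of 2.5 kb each side, the ratio of introns was 0.936, below 1.

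The replicates were compared peak by peak. Of replicate 1 peaks 37.6% overlapped a replicate 2 peak over at least 50% of their length, and of replicate 2 peaks 44.2% overlapped replicate 1, against 2.69% and 2.96% after circular shifts. The replicate 1 and replicate 2 shares were 28.6% and 72.2% on chromosome X, and 38.6% and 42.3% on the other chromosomes. The Jaccard index of covered bases was 0.407 against 0.0149 after shifts. Peaks of the highest fold were shared most often within each list. The share was 23.8% in the lowest and 88.1% in the highest of 10 equal bins of fold in replicate 1, and 23.5% and 94.7% in replicate 2. Of pooled peaks 32.9% were in the replicated list, 5.23% of those in the lowest bin of fold and 98.6% in the highest. By length, the share was 0.0933% in the shortest of 10 equal bins and 99.1% in the longest. Fold and length were not separated. At promoters, the covered bases of the replicates had a Pearson correlation of 0.958 and a Spearman correlation of 0.848 across genes, which are not independent replicates. Most of these genes were covered in neither replicate. Among the 7349 genes covered in either, Pearson's correlation was 0.922. A promoter was covered by at least 500 bases in 1 replicate and by none in the other at 106 genes for replicate 1 and at 66 for replicate 2. Of these, 22 and 3 lay on chromosome X. With windows of 2.5 kb each side the numbers were 8 and 4. That setting raised the minimum in proportion and required no covered base in the wider window of the other replicate, so its rule was stricter. The shared share of replicate 1 peaks was 22.7% when 80% of the peak had to be covered, and for replicate 2 it was 29.2%.

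**Figure D3:**
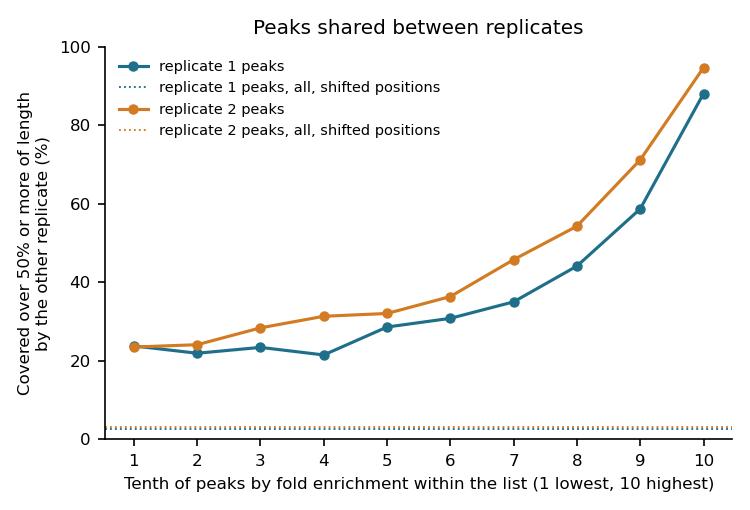
Share of peaks, in percent on the y axis, overlapped over at least 50% of their length by a peak of the other replicate, by bin of fold over control on the x axis (1 lowest, 10 highest), with 1 line per replicate and dotted lines for shifted positions. The share was 88.1% in the highest bin of replicate 1 and 94.7% in that of replicate 2, against 2.69% and 2.96% for all peaks at shifted positions.

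Coverage was also compared between chromosomes. Chromosome X had 4.06% of its length covered by 16712 peaks in replicate 1 and 1.99% by 9113 peaks in replicate 2. The median autosome had 2.76% covered in replicate 1 and 2.68% in replicate 2, and of the autosomes chromosome 3 was lowest (1.63% and 1.51%) and chromosome 19 highest (4.74% and 4.55%) in both replicates. The ratio of replicate 1 to replicate 2 peaks was 1.83 on chromosome X and 1.05 to 1.10 on the 19 autosomes, so the replicates differed on X by more than on any autosome. In the replicated list X had 3.22% covered, 1.18 times the median autosome, a value that lay between those of the replicates (1.47 and 0.745 times). At promoters, 20.6% of X-linked genes were covered by at least 500 bases in replicate 1 and 14.7% in replicate 2, while autosomal genes gave 18.4% and 17.9%. No peak lay on chromosome Y. With 1 list per replicate, the difference between pools was not tested against variation among pools.

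**Figure D4:**
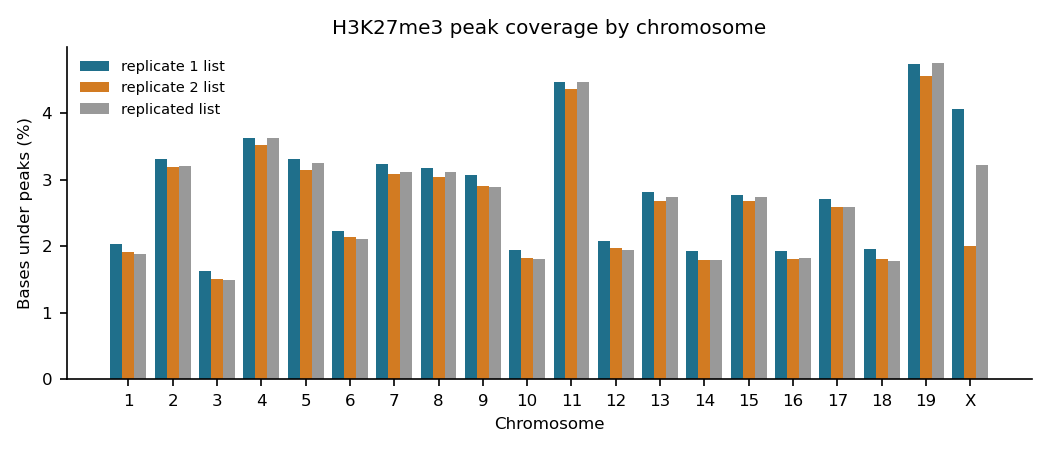
Percent of each autosome and of chromosome X covered by peaks, on the y axis, for the replicate 1 list, the replicate 2 list and the replicated list, by chromosome on the x axis. Chromosome X had 4.06% covered in replicate 1 and 1.99% in replicate 2, and of the autosomes chromosome 3 was lowest in both.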

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

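The alternatives with peaks overlapping each replicate by at least 50%, autosomes only for promoter counts and long domains, and 10 bins of CpG content were chosen after the data were seen. Of 383 planned values for gene lists, 354 kept their direction and their side of the threshold, 13 lost the call, 15 gained it and 1 reversed, and of 52 added values 48 kept both, 3 lost the call and 1 gained it. All 40 values for lists in long domains kept both, and of 77 values for contrasts 73 did and 4 gained the call. No alternative for long domains counted neighbouring members once. Except where the alternative removes genes or peaks by construction, the cause was not tested. Between 3115 genes (at least 1000 bases covered) and 5546 genes (any overlap of 1 base) were marked. Values for lists are log2 odds ratios, or for shifts and CpG bins log2 ratios of marked to expected members. Shifted peaks rarely meet a promoter (0.891 of 23 progenitor genes, 1.57 of 32 Polycomb group genes, 1.25 of 30 housekeeping genes), so calls gained or lost with shifts do not bear on a comparison with other genes. Neural progenitor genes passed with 1.63 (0.5 kb windows), 1.61 (2.5 kb), 1.62 (any transcript start) and 2.61 (shifts), and pan-neuronal genes with 1.62 (any transcript start), 1.97 (CpG-rich promoters) and 2.41 (shifts). Polycomb group genes passed with 2.04 (shifts). Imprinted genes passed with 1.31 (fold of at least 3), 1.42 (0.5 kb), 1.37 (2.5 kb), 1.56 (1000 bases), 1.31 (overlap with each replicate), 2.60 (shifts) and, leaving out each replicate, 1.41 to 1.55. Endothelial genes lost the call with 1.59 (pooled list), 1.38 (1 base) and 0.97 (CpG bins), and oligodendrocyte and astrocyte genes with 1.67 (neighbours once). Kinase inhibitors lost it with 2.14 (pooled list), 2.23 (1000 bases), 2.29 (no tandem families), 1.73 (CpG-rich promoters), 2.06 (neighbours once) and 1.36 (CpG bins). Housekeeping genes lost it with -1.54 (2.5 kb) and -1.81 (shifts) and without replicate 1, with -2.15 to -2.08 leaving out each replicate. Keratin-associated protein genes lost it with -2.34 (neighbours once), -0.97 (shifts) and -1.98 (CpG bins). Vomeronasal receptor genes turned to 0.14 among CpG-rich promoters, where almost no member remains and the 0.5 added to each count sets the value, and olfactory receptor and keratin-associated protein genes have no value there because no member remains. Lists called as marked less often numbered 1 without tandem families, 1 among CpG-rich promoters and 2 with shifts. Contrasts called numbered 2 with a fold of at least 3, with 1000 bases and with overlap with each replicate, and 1 to 2 leaving out each replicate, the added call being Hox against midbrain and isthmus patterning genes with 4.62 in each of the first 3 settings and 4.16 to 4.62 leaving out each replicate.

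With a fold of at least 3, the lists held 72405 (replicate 1), 54221 (replicate 2), 43600 (pooled) and 40075 (replicated) peaks. Shared peaks of replicate 1 and replicate 2 were 48.1% and 54.6% at 1 base, 22.7% and 29.2% at 80% of the peak, 26.0% and 29.1% at 50% of both peaks, 39.8% and 44.8% at a -log10 q of at least 2, and 39.2% and 41.7% with equal numbers of peaks. The Jaccard index was 0.434 at a -log10 q of at least 2 and 0.409 with equal numbers. With windows of 2.5 kb each side, ratios to the genome were 5.57 for promoters, 1.63 for exons, 0.936 for introns and 0.666 for intergenic sequence, and on the pooled list 4.25, 1.75, 1.07 and 0.792. Leaving out each replicate, they were 5.22 to 5.44, 1.90 to 1.97, 1.06 to 1.06 and 0.745 to 0.755. Long domains numbered 268 with gaps of 1 kb, 737 on the pooled list and 1280 with at least 10 kb covered. Across promoters Pearson's correlation was 0.974 with windows of 2.5 kb each side and 0.957 at a -log10 q of at least 2, and Spearman's was 0.866 with the former. Promoters found in 1 replicate only were 8 and 4 with the former, where the minimum of covered bases was raised in proportion to the window. Of 1864 values for single named genes, 1564 stayed within the spread between replicates and 300 did not. The depth of each list is unknown, so its effect on the number of peaks could not be tested.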

Other observations

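The gene families, miRNAs and unmarked genes of long domains named here were chosen after their values were seen, and the comparison of peaks on X with the autosomes, the long domains of X and the test within 10 bins of CpG content were also chosen after the results were seen. Genes were grouped by the first 3 letters of the symbol, where at most 1 more letter stood before the digit, which can mix gene families, and 245 such groups of at least 10 genes were tested by Fisher's exact test, of which 32 were marked more often and 17 less often than other genes. Of 81 genes with symbols in Kcn, mostly potassium channel subunits, 60 were marked, 68.5% ± 0.873 by the replicates' own lists (SD, n = 2, adjusted p = 1.34e-24, Fisher's exact test). Of 18 genes with symbols in Htr, which are serotonin receptors and a few proteases, 15 were marked (adjusted p = 2.22e-07, Fisher's exact test), and of 45 with symbols in Col, mostly collagens, 28 were (adjusted p = 9.59e-09, Fisher's exact test). Of 28 genes with symbols in Fgf, which are growth factors, their receptors and others, 16 were marked, of 22 in Syt, synaptotagmins and their relatives, 13, and of 18 in Scn, sodium channel subunits and others, 10. Shares of the Kcn, Htr and Col genes exceeded those of other genes in both replicates. Genes with symbols in Zfp, mostly zinc finger genes, were marked in 22 of 397 cases (adjusted p = 8.32e-14, Fisher's exact test) and histone genes (His) in 0 of 67 (adjusted p = 2.18e-05, Fisher's exact test), and how reads map among their similar copies was not measured.

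Of 2201 miRNA genes 190 (8.63%) were marked around the hairpin, and the copies of Mir9 and of Mir124a differed. The region around Mir9-1 was covered over 100% and that around Mir9-3 over 73.2%, while Mir9-2 had none, where Mir9 is a neural miRNA with 3 copies. Mir124a-1, a copy of another neural miRNA, had 69.9% covered, and Mir124a-2 and Mir124a-3 had none. The miRNAs of the Hox clusters, Mir10a, Mir10b, Mir196a-1, Mir196a-2, Mir196b and Mir615, had 100% covered. These windows lie around the hairpin, not around a transcription start. Of 448 protein-coding genes starting in long domains 15 (3.35%) were not marked, among them the progenitor factor gene Hes1 with 19.7% of its own window covered, and Irx3 with 17.5%. Hes1 started in a domain with 110 kb covered (domain at chromosome 16, 29999399 to 30158767). On chromosome X 23 of 41 long domains held no protein-coding start, against 131 of 397 elsewhere (p = 0.0054, Fisher's exact test, odds ratio 2.59, 95% interval 1.29 to 5.29). This comparison was not adjusted for gene density, with 948 protein-coding genes on the 171 Mb of X and 20780 on the autosomes. It also rests on X coverage that differed between the replicates (4.06% in replicate 1 and 1.99% in replicate 2).

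Replicate 1 held more X peaks than replicate 2. It also held more peaks on each of the 19 autosomes, at a ratio of 1.05 to 1.10. The ratio on X was 1.83, so a general excess of peaks in replicate 1 is argued against as the whole cause. An even shift of X copy number between a pool and its control would leave the bases covered in replicate 1 only unrelated to gene starts, but their Spearman correlation over 168 bins of 1 Mb was 0.490 (permutation p = 1.00e-05, the smallest that 100000 permutations can give), and since autosomes, which have no such shift, gave 0.187 to 0.742, the test decides nothing. Mark of the inactive X that spares escape genes could leave them with a smaller gain, and the gain of 5 escape genes minus that of 170 other X-linked genes with a CpG-rich promoter was -0.853 percentage points (means of 3.82 against 4.67, permutation p = 0.815), while the medians lay the other way (0.874 against 0.205), too few genes to decide. Per the labels the controls differed, with 1 control file for replicate 1 and 2 for replicate 2, and the pools may also differ in their share of female embryos, which the labels do not give, so that controls and pools cannot be told apart here.

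The 15 lists marked more often than other genes hold mostly developmental regulators and also receptor, vascular, glial and kinase inhibitor genes. Some of these lists share members, so their calls are not independent. CpG observed over expected at the annotated start is argued against as the whole cause. Within 10 bins of it, 13 of the 15 lists kept the call. The ratio was taken over 1 kb around 1 start per gene, where 20 of 39 Hox promoters were CpG-rich. GC content, and CpG islands away from that start, were not matched, so the bins do not decide on them. With neighbours counted once 13 of the 15 lists kept the call, but the step bears only on lists that lost members. Hox genes kept the call with 4 of 39 members left, Wnt ligands with 15 of 19 and the transcription factor families with 111 of 125. For these lists, clusters of neighbouring genes counted many times are argued against as the whole cause. The dopaminergic, the GABAergic and glutamatergic and the endothelial lists lost no member, so the step could not change them. Most other lists lost few. Within bins of CpG content the calls of endothelial genes (7 marked against 3.32 expected) and kinase inhibitors (4 against 1.25) ended, and with neighbours counted once those of oligodendrocyte and astrocyte genes (log2 odds ratio 1.67 against 1.88 before, with 14 of 15 members left) and kinase inhibitors (2.06 against 2.42, with 6 of 7 left), where fewer members were tested and the ratios stayed close. The design has 1 group, so no biological explanation for the calls of these 15 lists as a set was tested.

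Midbrain regulators were marked in midbrain. A candidate explanation is that the mark lies on a part of the cells of the pool, which would give these genes a lower fold than forebrain regulators. The median fold of marked midbrain and isthmus patterning genes was 8.13 and that of marked forebrain patterning genes 9.61, a difference of -1.48 (permutation p = 0.173), so the test did not decide. Mixed cell types and partial marking cannot be told apart in peak lists without counts.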
